A study of Mus musculus with 24 samples.

How the data were processed

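RNA from inguinal white adipose tissue of 24 mice was sequenced from the 3' end of transcripts with the QuantSeq library kit, and each library came from a separate mouse. The authors deposited a table of raw count values, in whole numbers per Ensembl gene, and a table of signal values, which are the same counts divided by 1 size factor per library. The processing notes of the submitters name R 3.4.3, DESeq2 1.18.1 and the mouse build GRCm38. The aligner, the counting program and the annotation are not given in the sources used here. Recomputing the counts from the signal values and 1 factor per library left a largest deviation of 6.05e-09 counts. The deposited count table held 17541 genes, each with a total of at least 72 counts over the 24 libraries, which is 3 per library on average.

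The raw counts were used for every result. Gene symbols were taken from the table for 14606 genes and from a reference annotation for 2888 more, and 47 genes had no symbol. Positions came from that annotation, which matched 17494 identifiers. Library totals ran from 8.62 to 21.9 M counts.

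Counts were normalised with trimmed mean of M values factors and filtered with filterByExpr, which kept 15939 genes and removed 1602. The quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 was fitted to all 24 libraries with a term for the group and robust estimation, which left 20 residual degrees of freedom. The common biological coefficient of variation was 0.621. Adjusted p values are Benjamini-Hochberg values over the 15939 genes, and a gene was called at an adjusted p under 0.05. Fold changes are given as log2 values with a standard error (SE), computed as the absolute log2 change divided by the square root of the F statistic. Expression is given as CPM, the counts of a gene divided by the library total in M counts times the normalisation factor of the library. That total is over the genes kept by the filter. CPM values stand with the standard deviation (SD) over the mice of a group. Log2 CPM used a prior count of 2.

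The comparisons were Aged CTRL minus Young CTRL, Aged BAM15 minus Aged CTRL, Young BAM15 minus Young CTRL, the difference between both BAM15 effects (the interaction), and Aged BAM15 minus Young CTRL. The series names Young CTRL as the reference. Replicate numbers were read as names of mice, not as pairs: across genes, the deviations from the group mean correlated with a median r of -0.04 in the 33 pairs of libraries with the same number in different groups, against 0.00 in the 182 other pairs, and 3 of 24 libraries had their best match in a library of their own number. A comparison of counts within the 61 pairs of mice of the same group gave a chi-square per gene of 19.8 to 644, so no library was a copy of another of its group.

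Before the data were examined, 42 gene lists were fixed from textbook knowledge: pathways of lipid and energy metabolism, stress and clock genes, cell type markers, and markers of tissue that can be taken with the depot. Each list was tested with camera of limma 3.58.1 on log2 CPM with a preset correlation of 0.01, and p values were adjusted over the 42 lists within a comparison. Beside it stand camera with an estimated correlation and fry, which tests whether the genes of a list move one way on balance and does not compare them with other genes. Members past the threshold were counted over all genes and adjusted over the list alone. The mean log2 CPM of each list was also compared between groups with a two-sided exact permutation test over the mice, adjusted over the 42 lists.

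The rule for naming genes, fixed at the same time, takes up to 8 genes per direction with the largest fold among called genes with a mean of at least 5 CPM, without predicted genes, in the age comparison and both BAM15 comparisons. It also takes 2 to 4 members of each list described (those with the smallest adjusted p, or the 2 most expressed where fewer passed), 8 fixed genes (Ucp1, Lep, Adipoq, Fasn, Itgax, Cdkn2a, Cdkn1a and Gdf15), and up to 6 genes per direction with the smallest adjusted p in the interaction. A last part, for genes called with age and called the other way by BAM15 in aged mice, found no gene. Which lists are described with members was chosen after the list results were seen, as were the 8 genes with the smallest p in each of the 2 BAM15 comparisons and in the comparison of Aged BAM15 with Young CTRL. In the age comparison C130026I21Rik, Gpnmb, Slc37a2, Trem2 and Mmp12, and in aged mice with BAM15 Trem2, Lgals3 and Gpnmb, were also named after their values were seen. The results of 4 genes that these choices reached are not reported here.

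Alternatives fixed at that time were DESeq2 size factors and upper-quartile factors, no filter and a filter of at least 1 CPM in at least 5 libraries, the DESeq2 1.42.0 Wald test, limma-voom with sample quality weights, a fit to the compared groups alone, the replicate number as a block, 1 surrogate variable from sva 3.50.0, covariates for the B cell and skeletal muscle lists, an added limit on the log2 fold change of 1, and leaving out each library in turn. Added after the data had been seen were fits without 4 libraries with mt-Rnr2 under 0.5% of counts, without 2 libraries with more than 50 CPM of the skin keratin Krt14, with a term for those 4 libraries, and with that term and both tissue covariates.

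The pipeline was tested on simulated data with the spread of these libraries, in which 50 genes each were changed 2, 4, 8 or 16 times. With edgeR, 5, 27, 39 and 44 of them were called in the age comparison, 9, 32, 37 and 42 with BAM15 in aged mice, and 13, 31, 42 and 45 with BAM15 in young mice. Of the genes left unchanged, 7, 2 and 3 were called by edgeR and 33, 30 and 18 by DESeq2. Shifted lists were called, and 0 of the other lists were, by camera with either correlation. Genes were drawn independently there, so this does not show how often lists of correlated genes are called in error. In the age comparison, other splits of the real libraries called up to 22 lists with the preset correlation. Comparisons that share control libraries were set against 20 simulated sets of unchanged groups, in which genes were again drawn independently. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. No library and no column of the count table was left out.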

Results

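Gene expression was measured in inguinal white adipose tissue, a fat depot under the skin, of C57BL/6J mice on a high-fat diet. The 24 mice fell into 4 groups: 7 Young CTRL and 6 Young BAM15 mice of 16 weeks, and 6 Aged CTRL and 5 Aged BAM15 mice of 92 weeks. BAM15 is a small molecule that uncouples mitochondria, and its dose is not in the labels. Library totals averaged 13.8 ± 3.61 M counts in Young CTRL (SD, n = 7), 11.3 ± 2.53 M in Young BAM15 (SD, n = 6), 15.0 ± 3.67 M in Aged CTRL (SD, n = 6) and 15.6 ± 4.33 M in Aged BAM15 (SD, n = 5). Transcripts of the mitochondrial genome made up 7.63 ± 2.05%, 6.26 ± 1.49%, 7.37 ± 3.74% and 11.6 ± 7.10% of counts in the same order (SD).

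The libraries also differed in ways that the groups do not name. In 4 libraries, Young CTRL 4, Aged CTRL 2, Aged BAM15 2 and Aged BAM15 5, the mitochondrial ribosomal transcript mt-Rnr2 held at most 0.257% of counts, against at least 0.722% in the other 20. These 4 lay apart on the first principal component, which held 29.0% of the variance. Mitochondrial transcripts made up 12.0 to 21.4% of their counts and at most 9.27% in the other 20, so the Aged BAM15 mean rests on Aged BAM15 2 and 5. B cell transcripts varied from library to library: the mean log2 CPM of the B cell list was 5.22 in Young CTRL 1, 5.25 in Young CTRL 5 and at most 0.352 in the other Young CTRL libraries. In Young BAM15 it was 4.99 to 6.98 in 5 libraries and -0.51 in the other. Acta1, the actin of skeletal muscle, reached 14063 CPM in Young CTRL 7 and 14545 CPM in Young BAM15 3. Krt14, a keratin of skin, reached 840 CPM in Young CTRL 1 and 90.0 CPM in Young CTRL 7, against at most 3.28 CPM elsewhere.

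**Figure D1:**
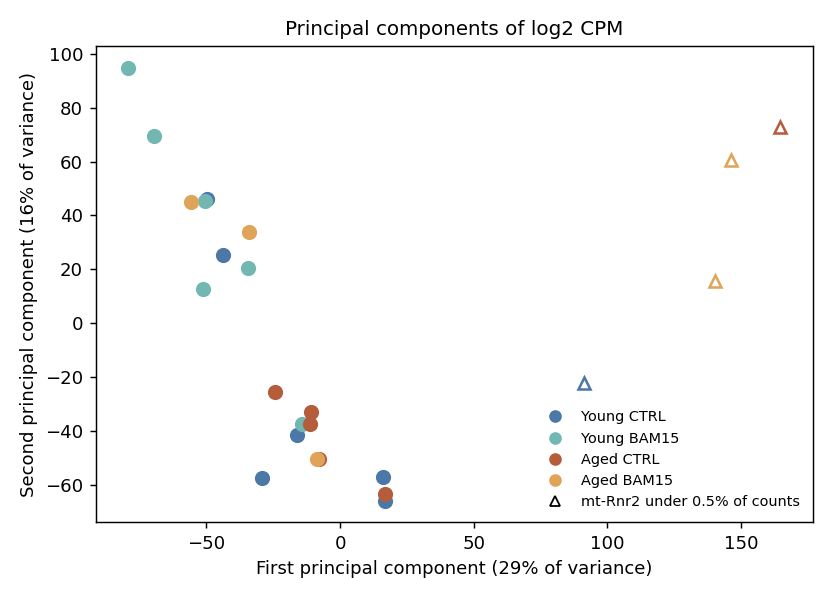
Principal components of log2 CPM, with the first component on the x axis (29.0% of variance) and the second on the y axis (16.0%), and 1 point per library coloured by group. The 4 open triangles are the libraries with mt-Rnr2 under 0.5% of counts, which lie to the right of the other 20.

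Aged CTRL was compared with Young CTRL to ask how age alters the depot on this diet. Fasn, which makes fatty acids, lay at 936 ± 216 CPM in Young CTRL (SD, n = 7) and 273 ± 108 CPM in Aged CTRL (SD, n = 6), a fall of 3.43-fold. Thbs2, a matricellular glycoprotein, rose 5.14-fold, from 22.2 ± 9.37 CPM (SD, n = 7) to 114 ± 47.9 CPM (SD, n = 6). The metallothionein gene Mt2, whose product binds zinc, rose 5.54-fold, from 159 ± 83.1 CPM (SD, n = 7) to 881 ± 609 CPM (SD, n = 6). Dbp, a transcription factor driven by the circadian clock, rose 4.20-fold.

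With edgeR, 33 of 15939 genes were called, 24 higher and 9 lower in Aged CTRL, all by at least 2-fold. Among the 8 genes with the largest rise were Ccn5 (log2 2.89 ± 0.50 SE, adjusted p = 0.0106), Prg4 (2.64 ± 0.48, 0.0118), Mt2 (2.47 ± 0.43, 0.0106), Thbs2 (2.36 ± 0.33, 0.0012), Cux2 (2.36 ± 0.36, 0.00364), Gnal (2.36 ± 0.39, 0.00973) and Vnn1 (2.22 ± 0.47, 0.0364). Prg4 encodes lubricin and Vnn1 a pantetheinase. The named genes that fell were Zfp185 (-1.92 ± 0.26, 0.00111), the neurotrophin receptor Ntrk3 (-1.80 ± 0.33, 0.014), Fasn (-1.78 ± 0.34, 0.0203), the lipid droplet enzyme Pnpla3 (-1.29 ± 0.26, 0.0317), the skin protein Cdsn (-1.28 ± 0.27, 0.0364) and Arap2 (-1.08 ± 0.19, 0.0106). Each of these 13 genes lay on the stated side of the Young CTRL mean in 6 of 6 Aged CTRL libraries. They were picked by their calls in these libraries, so that is no separate support. Thbs2 lies on chromosome 17 from 14665500 to 14694235, Fasn on chromosome 11 from 120805846 to 120824547, and Zfp185 on chromosome X from 72987339 to 73031543.

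The gene with the smallest adjusted p was C130026I21Rik, a predicted gene of chromosome 1 with near-identical copies beside it, so its reads cannot be placed with certainty. It lay at 37.0 ± 22.2 CPM in Aged CTRL (SD, n = 6) and 0.467 ± 0.332 CPM in Young CTRL (SD, n = 7), with a log2 change of 6.28 ± 0.54 and an adjusted p = 2.35e-07. It was named after its value was seen.

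Genes of fatty acid synthesis fell as a group. The list ranked lower in Aged CTRL (camera, adjusted p = 2.13e-09), which held with an estimated correlation (adjusted p = 0.0121). Of its 19 measured members, 2 fell over all genes and 9 fell when adjusted over the list alone, led by Fasn and Pnpla3. The mean log2 CPM of the list was 6.51 ± 0.190 in Aged CTRL (SD, n = 6) and 7.18 ± 0.164 in Young CTRL (SD, n = 7), with an adjusted exact permutation p = 0.0245. This difference of -0.68 was -0.62 without the 4 libraries with low mt-Rnr2, and its p of 0.00216, the smallest that the permutations can then give, was 0.0909 when adjusted. The mean log2 change of its members was -0.65, and -0.64 without those 4. Genes of cholesterol synthesis also ranked lower (camera, adjusted p = 6.27e-08), with 0 of 17 called over all genes and 12 lower when adjusted over the list alone. That call was lost with the estimated correlation (adjusted p = 0.136 with an estimated correlation). Hmgcs1, which acts early in the pathway, had a log2 change of -1.21 ± 0.40 and Msmo1 -1.63 ± 0.54, and these were -0.64 and -0.42 without Young CTRL 1, where Msmo1 lay at 530 CPM against at most 88.2 CPM in the rest of its group. The mean change of this list was -1.48, and -0.42 without Young CTRL 1.

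Brown and beige fat genes ranked lower (camera, adjusted p = 0.00142; adjusted p = 0.056 with an estimated correlation), with 0 of 16 members called over all genes and 2 lower when adjusted over the list alone. The mean log2 change was -0.74, and -0.61 without the 4 libraries and -0.41 without Young CTRL 1 and 7. Its most expressed members were Kcnk3, a potassium channel, at -0.10 ± 0.32, and Cox8b at -1.06 ± 0.69. Cox8b is also a muscle transcript and lay at 213 CPM in Young CTRL 7 and 83.1 CPM in Aged CTRL 1, where Acta1 was at 14063 and 5891 CPM, but also at 140 CPM in Young CTRL 4, where Acta1 was at 368 CPM. Its change was -0.50 without Young CTRL 7. Ucp1, the uncoupling protein of brown fat, was near the floor in every group, with 1.46 ± 2.80 CPM in Young CTRL (SD, n = 7) and 0.621 ± 0.827 CPM in Aged CTRL (SD, n = 6).

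Several immune lists ranked higher in Aged CTRL. Mast cell markers did so with both correlations (camera, adjusted p = 4.26e-07; adjusted p = 0.0297 with an estimated correlation), and all 12 had positive log2 changes, although 0 were called over all genes and 0 when adjusted over the list alone. The mast cell protease genes Mcpt4 and Tpsb2 had log2 changes of 1.92 ± 1.03 and 0.86 ± 0.49, and Mcpt4 lay at -0.37 without Aged CTRL 2. Cytokine and chemokine genes also ranked higher with both (camera, adjusted p = 1.05e-05; adjusted p = 0.0193 with an estimated correlation), with 2 of 21 higher when adjusted over the list alone and 0 over all genes. Ccl6 and Cxcl12 had log2 changes of 0.74 ± 0.35 and 0.29 ± 0.27. In exact permutation tests over the mice, both lists differed by 0.97 and 0.63 (adjusted p = 0.0367 for each). The differences were 0.95 and 0.58 without the 4 libraries with low mt-Rnr2, and with fewer mice neither passed (adjusted p = 0.0909 and 0.109).

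Macrophage markers (camera, adjusted p = 8.10e-09; adjusted p = 0.112 with an estimated correlation) had 4 of 24 members higher when adjusted over the list alone and 0 over all genes, with Lyz2 at 0.52 ± 0.33 and the protease Ctss at 0.72 ± 0.29. Lipid-associated macrophage markers, of cells that take up lipid from adipocytes (camera, adjusted p = 5.55e-07; adjusted p = 0.095 with an estimated correlation), had 1 of 19 higher over all genes and 4 when adjusted over the list alone. The member called was Gpnmb (log2 1.76 ± 0.34, adjusted p = 0.0206), and Slc37a2, a transporter of macrophages outside the list, was called too (1.44 ± 0.29, 0.0301). Trem2, a lipid receptor, had a log2 change of 1.48 ± 0.52 and Mmp12, the macrophage elastase, 1.48 ± 0.56, neither called. The most expressed members Apoe and Ctsb had log2 changes of 0.31 ± 0.32 and 0.52 ± 0.32. Interferon response genes (camera, adjusted p = 4.59e-08; adjusted p = 0.056 with an estimated correlation) had 12 of 27 higher when adjusted over the list alone and 0 over all genes. Their most expressed members were Psmb8 at 0.84 ± 0.41 and Irf1 at -0.30 ± 0.31. Psmb8 lay at 335 CPM in Aged CTRL 2 and at most 72.9 CPM in the rest of that group, and its change was 0.03 without Aged CTRL 2. The mean changes of the 3 lists were 0.58, 0.69 and 0.75, and 0.55, 0.72 and 0.58 without the 4 libraries with low mt-Rnr2.

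Antioxidant genes ranked higher (camera, adjusted p = 0.00117; adjusted p = 0.112 with an estimated correlation), with 2 of 20 higher over all genes, Mt2 and Mt1 (log2 1.89 ± 0.34, adjusted p = 0.0118), and 3 when adjusted over the list alone. Clock genes moved both ways (camera higher, adjusted p = 0.0117; adjusted p = 0.124 with an estimated correlation): Dbp (2.07 ± 0.38, 0.0118) and Per1 (1.28 ± 0.25, 0.0245) rose over all genes, and 5 of 16 rose and 2 fell when adjusted over the list alone. Cell cycle genes ranked lower (camera, adjusted p = 2.91e-06; adjusted p = 0.157 with an estimated correlation), with 0 of 22 lower over all genes and 1 when adjusted over the list alone, Top2a at -0.82 ± 0.40 and Pcna at -0.05 ± 0.20. The mean changes of the 3 lists were 0.43, 0.37 and -0.63, and 0.41, 0.38 and -0.65 without the 4 libraries. Of the other lists called, the nuclear respiratory chain ranked lower (0.487 with an estimated correlation), and immediate early genes (0.377), plasma cell markers (0.278) and mural cell markers (0.377) ranked higher.

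Of the fixed genes, Lep (leptin, log2 0.34 ± 0.57), Adipoq (adiponectin, 0.16 ± 0.31), Itgax (0.70 ± 0.41), and the senescence genes Cdkn2a (0.70 ± 0.71) and Cdkn1a (-0.11 ± 0.46) were not called with age. Gdf15, a stress-induced hormone, lay at 7.44 ± 4.56 CPM in Aged CTRL (SD, n = 6) and 1.95 ± 0.721 CPM in Young CTRL (SD, n = 7), with an adjusted p = 0.144. The count of 33 fell to 5 with the replicate number as a block, to 4 without the 2 libraries with skin keratin, to 18 in a fit to both groups alone, to 20 without Aged CTRL 6 and to 21 without Aged CTRL 1. It rose to 79 without the 4 libraries with low mt-Rnr2, and DESeq2 called 271 (124 higher and 147 lower) and limma-voom 147 (112 higher and 35 lower). Thbs2, Cux2, Zfp185 and C130026I21Rik kept their calls in every alternative run, and Vnn1, Cdsn, Per1, Pnpla3 and Slc37a2 lost theirs in 7 to 10 of the 13 fits that left out 1 library.

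**Figure D2:**
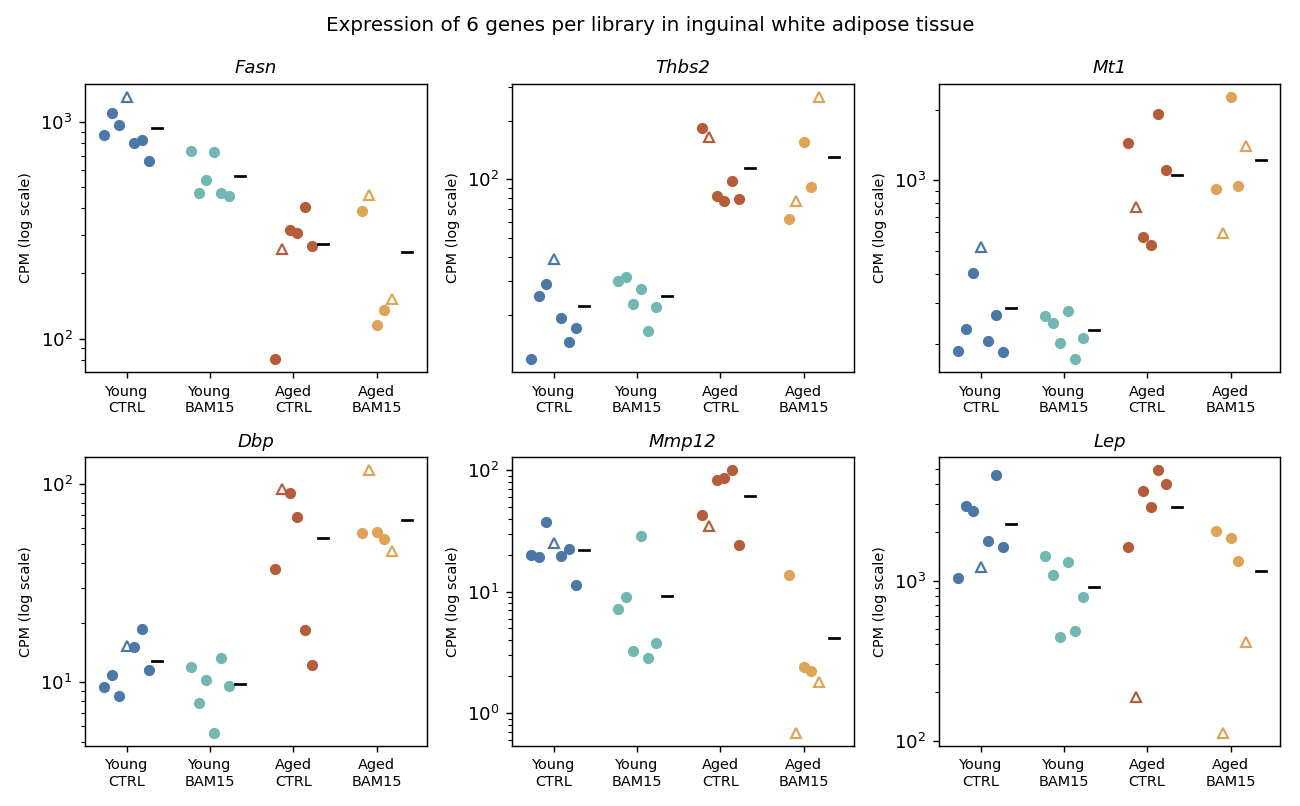
Expression of Fasn, Thbs2, Mt1, Dbp, Mmp12 and Lep in CPM on log axes, with 1 point per library, a bar for each group mean, and open triangles for the 4 libraries with low mt-Rnr2. Fasn averaged 936 CPM in Young CTRL and 273 CPM in Aged CTRL, and Mmp12 averaged 61.9 CPM in Aged CTRL and 4.17 CPM in Aged BAM15.

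Aged BAM15 was compared with Aged CTRL to ask what BAM15 does in old mice. Genes of lipid-associated macrophages ranked lower in Aged BAM15, the group with the smallest p in this comparison. Mmp12, the macrophage elastase, averaged 61.9 ± 31.7 CPM in Aged CTRL (SD, n = 6) and 4.17 ± 5.40 CPM in Aged BAM15 (SD, n = 5), a log2 change of -3.89 ± 0.71 that was not called (adjusted p = 0.105). Trem2 had a log2 change of -2.51 ± 0.61 and Lgals3, galectin-3, -2.04 ± 0.53, neither called. Without Aged BAM15 1, Mmp12 (-5.12), Trem2 (-3.20), Lgals3 (-2.62) and Itgax (-2.53) were called. In that library Trem2 lay at a log2 CPM of 3.45, against 1.00 to 1.70 in the rest of its group. Leaving it out thus widens the difference, and these calls add no support. The count of 0 called genes moved in 3 of the 11 fits that left out 1 library. Lep lay at 2873 ± 1715 CPM in Aged CTRL (SD, n = 6) and 1146 ± 853 CPM in Aged BAM15 (SD, n = 5), with a log2 change of -1.33 ± 0.64.

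With edgeR, 0 of 15939 genes were called and 1450 had an unadjusted p under 0.05, against 797 that chance gives. That number was 3055 without Aged CTRL 2 and 911 in a fit to both groups alone. DESeq2 called 140 genes and limma-voom with quality weights 964. Among the 8 genes with the smallest p were Mmp12, the transporter Slc37a2 (log2 -1.75 ± 0.33), the vessel growth factor Angpt1 (1.13 ± 0.22), Adam8 (-2.21 ± 0.44), the lysosomal protease gene Lgmn (-0.96 ± 0.20), the growth factor Hbegf (-2.01 ± 0.44) and Zfp185 (1.27 ± 0.27), with adjusted p values from 0.105 to 0.206. In all 7, each of the 5 Aged BAM15 libraries lay on that side of the Aged CTRL mean. The genes were picked by their p in these same libraries, so this adds no separate support. Mmp12 lies on chromosome 9 from 7344381 to 7369499. Itgax (-1.90 ± 0.47), Cdkn1a (-1.90 ± 0.53), Gdf15 (-1.25 ± 0.56), Fasn (-0.12 ± 0.36), Adipoq (-0.38 ± 0.33) and Cdkn2a (-0.13 ± 0.78) were not called. Ucp1 lay at 0.117 ± 0.261 CPM in Aged BAM15 (SD, n = 5).

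The list of lipid-associated macrophage markers ranked lower with both correlations (camera, adjusted p = 3.99e-14; adjusted p = 0.0261 with an estimated correlation), with 0 of 19 called over all genes and 12 lower when adjusted over the list alone. Its most expressed members were Apoe, at 0.19 ± 0.35, and Ctsb, at -0.43 ± 0.35, and Gpnmb lay at -1.07 ± 0.37. The mean log2 change was -1.23, and -1.16 without the 4 libraries with low mt-Rnr2. The mean log2 CPM of the list was 5.48 ± 0.432 in Aged BAM15 (SD, n = 5) and 6.74 ± 0.503 in Aged CTRL (SD, n = 6), and the exact permutation p of 0.00649 gave an adjusted p of 0.197. Macrophage markers ranked lower (camera, adjusted p = 6.86e-05; adjusted p = 0.347 with an estimated correlation), with 8 of 24 lower when adjusted over the list alone, among them Ctss (-0.87 ± 0.32), and 0 over all genes. Lyz2 had a log2 change of -0.60 ± 0.37. Their mean change was -0.45, and -0.57 without the 4 libraries.

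Collagen and matrix genes ranked lower (camera, adjusted p = 3.08e-07; adjusted p = 0.323 with an estimated correlation), with 5 of 26 lower when adjusted over the list alone and 0 over all genes. Sparc, a collagen-binding protein, and Col3a1 had log2 changes of -1.03 ± 0.36 and -1.04 ± 0.35, and both fell when adjusted over the list alone. Cell cycle genes ranked lower (camera, adjusted p = 3.23e-05; adjusted p = 0.323 with an estimated correlation), with 1 of 22 lower when adjusted over the list alone, Top2a at -0.98 ± 0.44, which was -0.36 without the 4 libraries with low mt-Rnr2, and Pcna at -0.05 ± 0.22. Interferon response genes ranked lower (camera, adjusted p = 0.00333; adjusted p = 0.347 with an estimated correlation), with 1 of 27 lower when adjusted over the list alone, and Psmb8 (0.05 ± 0.44) and Irf1 (0.14 ± 0.34), its most expressed members, were not called. Fatty acid oxidation genes ranked lower (camera, adjusted p = 0.00333; adjusted p = 0.347 with an estimated correlation), with 0 of 20 called over all genes or when adjusted over the list alone, Acsl1 at -0.69 ± 0.29 and Hadh at 0.56 ± 0.42, or -0.22 without those 4. Senescence genes ranked lower (camera, adjusted p = 0.00665; adjusted p = 0.323 with an estimated correlation), where Cdkn1a fell when adjusted over the list alone (1 of 19), and Igfbp4 had a log2 change of 0.27 ± 0.26. Over all genes, 0 members of these 4 lists were called. Without the 4 libraries the mean changes of the 5 lists were -0.55, -0.48, -0.37, -0.50 and -0.40, against -0.50, -0.67, -0.49, -0.30 and -0.66 with them.

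T cell markers ranked higher in Aged BAM15 (camera, adjusted p = 0.00333; adjusted p = 0.787 with an estimated correlation), with 0 of 22 called over all genes and 0 when adjusted over the list alone, Trbc2 at 2.35 ± 1.00 and Bcl11b at 2.42 ± 1.21, or 1.48 without Aged BAM15 4. Their mean change was 1.79, or 2.77 without the 4 libraries and 0.87 with a term for them and the B cell and muscle covariates. Skeletal muscle genes were called higher, although their median log2 change was -0.37 and their mean -0.34 (0.787 with an estimated correlation). The test used log2 CPM, on which the mean of the list was 1.91 higher in Aged BAM15. The other lists called were immediate early genes, lower (0.347), and citric acid cycle (0.707), clock (0.323), nerve (0.471) and mesothelial genes (0.323), higher. Without the 4 libraries the citric acid cycle list was no longer higher, with a mean change of -0.024, and that of the clock list went from 0.30 to 0.06. The calls of the mesothelial and skeletal muscle lists were lost without Aged BAM15 1 (mean changes of 0.46 and -1.71), and that of the T cell list without Aged BAM15 4 (1.29). The count of 0 genes rose to 67 without Aged BAM15 1, to 17 without Aged CTRL 2 and to 1 without Aged CTRL 5.

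Young BAM15 was compared with Young CTRL to ask what BAM15 does in young mice. Genes of lipid handling and of lipid-associated macrophages ranked lower and lymphocyte genes higher by camera with the preset correlation, and 0 of these lists held with an estimated correlation. The B and T cell lists were also high in Young CTRL 1 and 5 and low in Young BAM15 1. Lep lay at 919 ± 415 CPM in Young BAM15 (SD, n = 6) and 2269 ± 1241 CPM in Young CTRL (SD, n = 7), a log2 change of -1.30 ± 0.58 that was not called. Mest, a gene linked to the expansion of fat mass, lay at 238 ± 116 CPM in Young BAM15 (SD, n = 6) and 823 ± 357 CPM in Young CTRL (SD, n = 7), a log2 change of -1.79 ± 0.41 that was not called.

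With edgeR, 0 of 15939 genes were called and 2081 had an unadjusted p under 0.05, against 797 that chance gives. With the B cell and muscle covariates 7 genes were called and 806 had such a p. That number was 1184 without Young BAM15 5, 1173 with the covariates and a term for the 4 libraries with low mt-Rnr2, and 3235 without those 4. DESeq2 called 218 genes and limma-voom with quality weights 679. The 8 genes with the smallest p all had lower means in Young BAM15, with adjusted p = 0.179: the cell cycle kinase Cdk1 (log2 -1.35 ± 0.28), Pcolce2 (-1.48 ± 0.31), Plpp2 (-1.13 ± 0.24), Irx1 (-3.29 ± 0.70), Ttc39c (-1.37 ± 0.30), the calcium pump Atp2a2 (-0.74 ± 0.17), the complement component C6 (-1.45 ± 0.33) and Mest. Each lay below the Young CTRL mean in 6 of 6 libraries. Since they were picked by their p in these libraries, that is no separate support. Irx1 lay at 45.2 CPM in Young CTRL 1 and at 1.57 to 10.3 CPM in the rest of that group, and its change was -2.25 without Young CTRL 1. Fasn (-0.72 ± 0.33), Adipoq (-0.50 ± 0.31), Itgax (-0.58 ± 0.41), Cdkn2a (0.87 ± 0.72), Cdkn1a (-0.74 ± 0.47) and Gdf15 (-1.16 ± 0.53) were not called, and Ucp1 lay at 1.49 ± 2.35 CPM in Young BAM15 (SD, n = 6).

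Cholesterol synthesis genes ranked lower (camera, adjusted p = 1.19e-07; adjusted p = 0.196 with an estimated correlation), with 0 of 17 called over all genes and 14 lower when adjusted over the list alone, among them Hmgcs1 (-1.45 ± 0.40) and Msmo1 (-1.99 ± 0.55). Without Young CTRL 1 these 2 lay at -0.88 and -0.79, and the mean change of the list went from -1.62 to -0.57. Lipid-associated macrophage markers ranked lower (camera, adjusted p = 1.69e-07; adjusted p = 0.126 with an estimated correlation), with 5 of 19 lower when adjusted over the list alone and 0 over all genes, Apoe at 0.63 ± 0.32 and Ctsb at -0.57 ± 0.32. Fatty acid synthesis genes ranked lower (camera, adjusted p = 0.000132; adjusted p = 0.126 with an estimated correlation), with 5 of 19 lower when adjusted over the list alone and 0 over all genes, Scd1, a desaturase, at -0.04 ± 0.34 and Fasn at -0.72 ± 0.33. The mean log2 CPM of these 3 lists differed by -0.92, -0.77 and -0.43, with an adjusted exact permutation p = 0.0367 for each. Without the 4 libraries with low mt-Rnr2 the mean changes were -1.73, -0.74 and -0.48, and the list means differed by -1.01, -0.80 and -0.41, but with 1 mouse fewer the permutation test called 0 of them (adjusted p = 0.0909 for each).

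Triglyceride genes ranked lower (camera, adjusted p = 0.00154; adjusted p = 0.196 with an estimated correlation), with 4 of 14 lower when adjusted over the list alone, among them the lipase Mgll (-0.83 ± 0.31), while Pck1 lay at 0.38 ± 0.38. Fatty acid oxidation genes ranked lower (camera, adjusted p = 5.67e-06; adjusted p = 0.158 with an estimated correlation), with 2 of 20 lower when adjusted over the list alone, among them Acsl1 (-0.88 ± 0.27), and Hadh at -0.73 ± 0.40. Collagen and matrix genes ranked lower (camera, adjusted p = 5.67e-06; adjusted p = 0.269 with an estimated correlation), with 1 of 26 lower when adjusted over the list alone, Sparc at -0.70 ± 0.33 and Col3a1 at -0.78 ± 0.32. Over all genes, 0 members of these 3 lists were called. With the term for the 4 libraries and both tissue covariates the mean changes went from -0.43, -0.46 and -0.47 to -0.17, -0.24 and -0.14.

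B cell markers ranked higher (camera, adjusted p = 4.51e-08; adjusted p = 0.269 with an estimated correlation), as did T cell markers (camera, adjusted p = 1.17e-08; adjusted p = 0.269 with an estimated correlation) and lymph node stroma (camera, adjusted p = 1.48e-06; adjusted p = 0.269 with an estimated correlation). None of the 17, 22 and 12 members was called over all genes or when adjusted over the list alone. Ighd, an immunoglobulin of naive B cells, had a log2 change of 2.12 ± 1.33, while Ighm lay at -0.45 ± 0.40. Trbc2 and Bcl11b had log2 changes of 1.87 ± 0.91 and 1.79 ± 1.08, and Cd52 and Clu 1.51 ± 0.61 and 1.37 ± 0.59. Single libraries moved these: Ighd and Trbc2 lay at 2.90 and 2.54 without Young CTRL 5, Bcl11b and Clu at 2.41 and 1.93 without Young CTRL 1, and Trbc2 and Bcl11b at 1.36 and 1.27 without Young BAM15 5. The mean log2 CPM of the B cell list was 4.77 ± 2.69 in Young BAM15 (SD, n = 6) and 1.48 ± 2.58 in Young CTRL (SD, n = 7), with an exact permutation p = 0.0577. With the B cell and muscle covariates, the T cell list had a mean change of -0.06.

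The other lists called lower in Young BAM15 were those of the integrated stress response (0.126), creatine cycling (0.126), glycolysis (0.196), antioxidants (0.269), senescence (0.269), the mitochondrial genome (0.314), the nuclear respiratory chain (0.314), the cell cycle (0.343), the citric acid cycle (0.441), epithelium (0.269) and brown fat (0.196), where the median log2 change of the brown fat list was 0.03 and its mean -0.49. Without Young CTRL 1 and 7 the mean changes of the creatine, glycolysis and epithelium lists went from -0.27, -0.38 and -3.11 to 0.32, 0.17 and 0.54. Without Young BAM15 3 those of the creatine and brown fat lists were -1.13 and -1.08, so single libraries moved them both ways. Called higher were cytotoxic lymphocyte (0.196), plasma cell (0.269), dendritic cell (0.343) and interferon response genes (0.269). The values in brackets are adjusted p values with an estimated correlation, with which 0 of the 24 lists called held. The count of lists fell from 24 to 8 with the B cell and muscle covariates, and the count of 0 genes rose to 1 without Young BAM15 3.

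**Figure D3:**
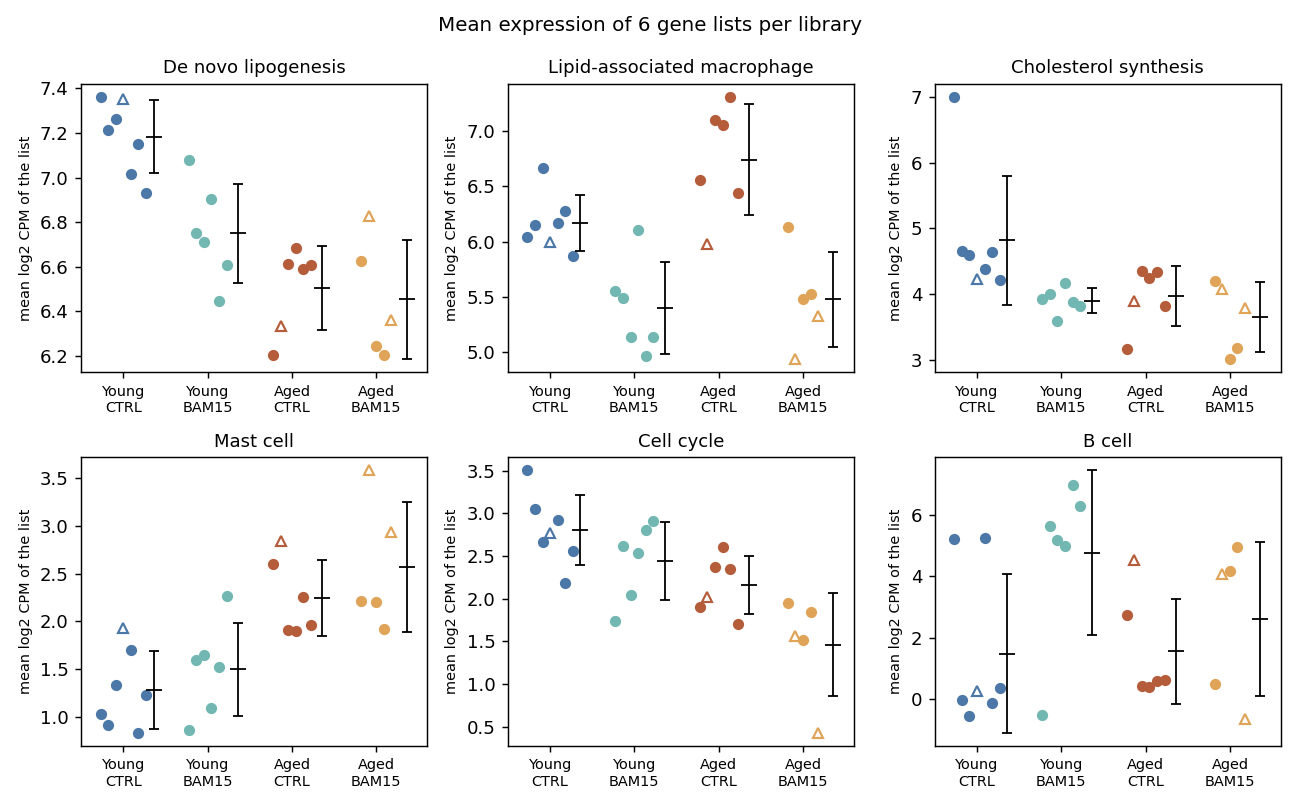
Mean log2 CPM of 6 gene lists on the y axis, with 1 point per library, the group mean ± SD beside it, and open triangles for the 4 libraries with low mt-Rnr2. The list of lipid-associated macrophage markers averaged 6.74 in Aged CTRL and 5.48 in Aged BAM15, and the list of de novo lipogenesis 7.18 in Young CTRL and 6.51 in Aged CTRL.

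The interaction asked whether the BAM15 effect differed between ages. Interferon response genes had the smallest p, and all 27 members had negative interaction values. Their mean BAM15 change was -0.49 in aged and 0.42 in young mice (camera, adjusted p = 7.57e-07; adjusted p = 0.369 with an estimated correlation). Psmb8, an immunoproteasome subunit, and Irf1 had interaction log2 values of -0.94 ± 0.60 and -0.27 ± 0.46, that of Psmb8 was -0.13 without Aged CTRL 2 and -0.36 without the 4 libraries with low mt-Rnr2, and 0 of the 27 members were called over all genes or when adjusted over the list alone. The mean interaction value of the list was -0.91, and -0.76 without those 4. Fatty acid synthesis genes had a mean interaction value of 0.47 (camera, adjusted p = 0.00314; adjusted p = 0.513 with an estimated correlation), with Scd1 at 0.86 ± 0.50 and Fasn at 0.60 ± 0.48 and 0 of 19 called over all genes or when adjusted over the list alone. Without the 4 libraries this mean was 0.29 and the value of Scd1 0.21.

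With edgeR, 0 of 15939 genes were called for the interaction and 809 had an unadjusted p under 0.05, against 797 that chance gives. That number was 2111 without Aged CTRL 2, 1303 without Aged BAM15 4 and 463 without Aged BAM15 5. DESeq2 called 38 and limma-voom 0. The genes with the smallest adjusted p that lay higher were Zfp185 (log2 1.79 ± 0.37), the homeobox gene Irx1 (4.41 ± 0.97), Slc25a15 (1.44 ± 0.36), the potassium channel Kcnk1 (6.17 ± 1.63), the clock-driven transcription factor Hlf (1.197 ± 0.324) and Mrgprg (2.96 ± 0.80). Those that lay lower were the myeloid receptor Clec12a (-1.99 ± 0.45), Slc37a2 (-1.75 ± 0.44), the macrophage perforin Mpeg1 (-1.64 ± 0.43), Ugt2b36 (-5.67 ± 1.60) and Rdh7 (-4.57 ± 1.29), and also Gm15337, which had 0 counts in Aged BAM15 and is given no fold. Their adjusted p values were 0.866 to 0.899. Ugt2b36 and Rdh7 lay at most at 6.24 and 7.44 CPM in any library, and their values were -7.95 without Aged BAM15 2 and -3.60 without Aged CTRL 4. Kcnk1 lay at 29.1 CPM in Young CTRL 1 and at most 1.72 CPM in the rest of that group, and without Young CTRL 1 the values of Kcnk1 and Irx1 were 3.43 and 3.36. The fixed genes Lep (-0.02 ± 0.84), Adipoq (0.12 ± 0.45), Itgax (-1.32 ± 0.61), Cdkn2a (-1.001 ± 1.06), Cdkn1a (-1.16 ± 0.69) and Gdf15 (-0.09 ± 0.81) were not called either, and those of Itgax and Cdkn2a were -0.70 and -0.075 without the 4 libraries with low mt-Rnr2, while Itgax was -1.95 without Aged BAM15 1. T cell markers were called lower for the interaction, although their median was 0.10 and their mean -0.040, and skeletal muscle genes higher, although their median was -0.68 and their mean -0.47. The test used log2 CPM, on which the T cell list differed by 1.17 with BAM15 in aged and by 2.29 in young mice. Of the 19 lists called, 0 held with an estimated correlation. The count of lists called was 7 without the 4 libraries with low mt-Rnr2 and 6 without Aged CTRL 2.

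Aged BAM15 was compared with Young CTRL, the reference of the series. Per3, a clock gene, rose 4.45-fold, from 35.0 ± 11 CPM in Young CTRL (SD, n = 7) to 155 ± 71.2 CPM in Aged BAM15 (SD, n = 5). Thbs2 rose 5.90-fold and Timp4, a metalloproteinase inhibitor, 4.72-fold. Fasn fell 3.74-fold, from 936 ± 216 CPM (SD, n = 7) to 250 ± 161 CPM (SD, n = 5), and Scd2, a desaturase, fell 5.55-fold. Top2a, a topoisomerase of dividing cells, fell as well.

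With edgeR, 205 genes were called, 123 higher and 82 lower, 178 of them by at least 2-fold. Among the 8 with the smallest p apart from C130026I21Rik were Thbs2 (log2 2.56 ± 0.35), Per3 (2.15 ± 0.29), Rprml (2.21 ± 0.33), the sialyltransferase gene St6galnac5 (2.28 ± 0.35), the protease gene Adam33 (1.90 ± 0.29), Timp4 (2.24 ± 0.35) and Tns2 (1.51 ± 0.24), with adjusted p values from 0.000677 to 0.00201. Each lay above the Young CTRL mean in 5 of 5 Aged BAM15 libraries. As these genes were picked by their p in the same libraries, this is no separate support. Of the genes called with age, 20 were also called here, 17 higher and 3 lower in both. Unrelated comparisons would give 0.185 and 0.0463, but these 2 share the Young CTRL libraries, which raises the overlap, and the simulated unchanged groups, with 0 genes called in both, do not show by how much. The log2 changes of both comparisons correlated across genes with r = 0.605. Sharing the Young CTRL libraries gave 0.433 in simulated unchanged groups, whose genes were drawn independently. Genes of the real libraries vary together, and no splits of them were run for this pair. Whether 0.605 exceeds what sharing gives was therefore not settled. Genes are not independent replicates, so no p is given for a correlation across genes.

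Cell cycle genes ranked lower (camera, adjusted p = 7.12e-12), with 1 of 22 lower over all genes and 15 when adjusted over the list alone, Top2a at -1.79 ± 0.44 and Pcna at -0.09 ± 0.21. Mast cell markers ranked higher (camera, adjusted p = 2.00e-05), with 0 of 12 over all genes and 6 when adjusted over the list alone, among them Mcpt4 (3.59 ± 1.11) and Tpsb2 (1.52 ± 0.51). Mcpt4 lay at 394 and 116 CPM in Aged BAM15 2 and 5 and at 11.3 to 15.5 CPM in the other 3, and its change was 1.64 without the 4 libraries with low mt-Rnr2, and 4.74 without Young CTRL 4, where it was called. Without Aged BAM15 2 the changes of Mcpt4 and Tpsb2 were 2.09 and 0.94. Fatty acid synthesis genes ranked lower (camera, adjusted p = 2.44e-05), with 5 of 19 lower and 1 higher over all genes and 8 lower and 1 higher when adjusted over the list alone. Those that fell included Acss2 (-2.05 ± 0.32), Scd2 (-2.47 ± 0.41), the citrate carrier Slc25a1 (-1.99 ± 0.35) and Fasn (-1.90 ± 0.37). Clock genes ranked higher (camera, adjusted p = 0.00056), with 6 of 16 higher and 1 lower over all genes and 7 higher and 2 lower when adjusted over the list alone. Dbp (2.37 ± 0.39), Hlf (1.28 ± 0.23) and Tef (2.45 ± 0.44, or 1.72 without those 4) rose beside Per3. Brown and beige fat genes ranked lower (camera, adjusted p = 0.00149), with 2 of 16 lower over all genes and 4 when adjusted over the list alone, Dio2, which activates thyroid hormone, at -4.30 ± 0.91 (at most 0.692 CPM in Aged BAM15, and -5.37 without Aged BAM15 5) and Gk, glycerol kinase, at -1.49 ± 0.38. These 5 lists held with an estimated correlation (adjusted p = 0.0494 for each). Their mean changes were -1.29, 1.5, -0.68, 0.67 and -1.18, and -1.14, 1.01, -0.82, 0.44 and -1.21 without the 4 libraries with low mt-Rnr2.

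Cholesterol synthesis genes ranked lower (camera, adjusted p = 1.02e-06; adjusted p = 0.228 with an estimated correlation), with 4 of 17 lower over all genes and 10 when adjusted over the list alone. Among them were Hmgcs1 (-2.08 ± 0.44), Nsdhl (-1.51 ± 0.34) and Insig1 (-1.54 ± 0.37), and without Young CTRL 1 the mean change went from -1.76 to -0.70 and that of Hmgcs1 to -1.51. Collagen and matrix genes ranked lower (camera, adjusted p = 1.14e-06; adjusted p = 0.302 with an estimated correlation), with 5 of 26 lower over all genes and 14 lower and 3 higher when adjusted over the list alone, among them Col3a1 (-1.94 ± 0.36), Col5a3 (-1.48 ± 0.29), Col6a2 (-1.41 ± 0.30) and Postn (-1.38 ± 0.32). Also called lower were fatty acid oxidation (0.311), lipid-associated macrophage (0.400) and nuclear respiratory chain genes (0.720), and higher were plasma cell markers (0.647), with adjusted p values with an estimated correlation in brackets. Cdkn1a (-2.01 ± 0.52, adjusted p = 0.0542), Lep (-0.99 ± 0.61), Itgax (-1.20 ± 0.45), Adipoq (-0.22 ± 0.32), Cdkn2a (0.58 ± 0.75) and Gdf15 (0.67 ± 0.53) were not called, while Itgax was called without Aged BAM15 1 (-1.84).

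The count of 205 rested on single libraries. It was 630 without Aged BAM15 1, 46 without Aged BAM15 5, 63 without Aged BAM15 2, 95 without Aged BAM15 3, 128 without Aged BAM15 4, 462 without Young CTRL 4, 109 without Young CTRL 2, 109 without Young CTRL 3, 130 without Young CTRL 5, 93 without Young CTRL 6 and 134 without Young CTRL 7. It was 105 without the 4 libraries with low mt-Rnr2, 86 without the 2 with skin keratin, 29 in a fit to both groups alone and 17 with the replicate number as a block. DESeq2 called 826 genes and limma-voom 1633, and the balance of directions turned: 380 were higher and 446 lower with DESeq2, 737 and 896 with limma-voom, and 162 and 194 in edgeR with a term for the 4 libraries. Top2a, Gk, Postn, Insig1, Nsdhl and Col6a2 lost their calls in 4 to 9 of the 12 fits that left out 1 library, and Thbs2, Per3, Acss2, Scd2, Rprml, St6galnac5, Adam33 and Tns2 kept theirs in every alternative run.

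The last comparisons set 2 sets of fold changes against each other across genes. With edgeR, 0 genes were called with age and called the other way by BAM15 in aged mice, and DESeq2 and limma-voom found 31 each. The age and BAM15 changes had r = -0.356 and rho = -0.22, but both use the Aged CTRL libraries with opposite signs, and simulated unchanged groups gave r = -0.493 ± 0.0147 (SD). Their covariance was -0.193, against -0.223 in the simulations. Over the 10869 genes with a mean of at least 5 CPM, r was -0.135 and rho -0.10. When the Aged CTRL libraries were split 3 and 3 between both comparisons, r averaged -0.02 and ran from -0.20 to 0.11. The BAM15 changes in aged and young mice, which share no libraries, had r = 0.312 and rho = 0.26, and simulated unchanged groups gave r = -0.00125 ± 0.0185 (SD). Other splits of the real libraries gave values as strong, up to -0.610, so chance cannot be excluded. The r of 0.312 was 0.149 without Aged BAM15 4.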

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

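The tests of a preparation difference and of age or BAM15 in the 4 libraries, and the tests of C130026I21Rik and of the clock genes, were chosen only after the result was seen. The test of depth and the splits of the libraries were planned.

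Young CTRL 4, Aged CTRL 2, Aged BAM15 2 and Aged BAM15 5, from 3 groups, stood apart on the first principal component by 0.306 of its range and differed from the other 20 libraries in 7413 genes, 3267 higher and 4146 lower. Depth was argued against: their totals were 18.4 to 21.9 M counts against 8.62 to 17.9 M, but after thinning of all libraries to 8.62 M the distance was 0.316 of the range. Age and BAM15 were argued against as the whole cause, since the 4 stood apart from mice of the same age and treatment. The 7413 genes differed with the group in the fit. Their count adds no separate support, because the 4 were picked as standing apart. A preparation that captured less RNA without a poly(A) tail may be the cause: over 97 such genes the median log2 difference was -2.90, with 52 lower and 0 higher, against -0.0978 over 13695 protein-coding genes, and on another measure, the plain difference in log2 CPM, which a prior count pulls towards 0, the median was -1.69, -1.71 and -1.98 within Young CTRL, Aged CTRL and Aged BAM15. The labels give no preparation date, so this stays a hypothesis found and tested on the same data.

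C130026I21Rik lay at 13.7 to 73.9 CPM in the 11 aged libraries and at 0.0843 to 1.39 CPM in the 13 young ones, on chromosome 1 from 84992690 to 85270566. Reads moved between the counted genes of the locus were argued against. Without C130026I21Rik these genes summed to 3.74 CPM in aged and 1.69 CPM in young libraries, so they were not higher in young ones. With it, the sum over the 5 counted genes was 16.3 times higher in aged libraries (37.7 against 2.31 CPM). Copies that were not counted could not be assessed. Another source colony for the aged mice cannot be told apart from age, because every aged mouse stands against every young one. Of 14228 genes with a mean of at least 1 CPM, 1 lay at least 4 times above or below in all aged libraries, and this was C130026I21Rik itself, so the count adds nothing on the source. Age itself was not tested as an explanation and stays open.

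Clock genes moved in opposite directions with age: the activator genes lay 1.39 log2 units lower in Aged CTRL than in Young CTRL (a difference of -1.39, exact permutation p = 0.00175), and the output genes 0.96 higher (exact permutation p = 0.00291). A larger share of cells rich in clock transcripts in aged mice was argued against by libraries outside this comparison: the activator genes, which it would raise, differed by -1.91 between Aged BAM15 and Young BAM15 (exact permutation p = 0.00216, the smallest that the permutations can give). The 4 libraries with low mt-Rnr2 were argued against as the whole cause, since the difference between both arms was 2.35 with them and 2.38 without them (exact permutation p = 0.00216, the smallest that the permutations can give). Between Aged BAM15 and Young BAM15 it was 3.66. Between Aged BAM15 and Aged CTRL it was 1.22 (exact permutation p = 0.0498), or 1.45 without the 4 libraries (exact permutation p = 0.0536). Between Young BAM15 and Young CTRL it was -0.09. Adjusted over the clock tests, the exact permutation p within aged mice was 0.0747, or 0.0804 without the 4 libraries. The activator genes alone differed there by -0.481 (exact permutation p = 0.201). Whether the arms also parted within aged mice was thus not settled. Collection at another time of day or another feeding state may explain the difference between young and aged mice, and cannot be told apart from age, since the labels give no times.

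Of 567 groups of values, 54 had a library far from the others of its group, where chance flags about 1 in 20 groups, or about 28. Aged CTRL 2 held 10 of them, Young CTRL 4 held 7, and Young CTRL 1 and Young BAM15 1 held 6 each. Values below are log2 CPM unless a unit is given, with the lowest and highest of the other libraries of the group in brackets.

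Young CTRL 4 lay above the others of its group in the total (M counts) 21.9 (11.5 to 13.3), the mitochondrial share (%) 12.0 (6.18 to 8.34), Mcpt4 5.28 (0.77 to 2.62), Per1 4.70 (3.77 to 4.15), Hadh 10.54 (8.50 to 9.10) and Tef 7.51 (6.14 to 6.70), and below them in sex chromosome genes 4.32 (5.04 to 5.33). Young CTRL 7 lay above the others of its group in creatine and calcium cycling genes 5.21 (3.94 to 4.16) and skeletal muscle genes 11.15 (0.92 to 4.34). Young CTRL 1 lay above the others of its group in cholesterol synthesis genes 7.00 (4.21 to 4.65), neutrophil genes 2.35 (0.39 to 1.08), Hmgcs1 11.34 (8.74 to 9.78) and Msmo1 9.05 (5.04 to 6.46), and below them in collagen and extracellular matrix genes 6.90 (7.97 to 8.18) and Col3a1 9.32 (10.49 to 11.37). Young CTRL 6 lay below the others of its group in mesothelial genes -0.11 (0.90 to 1.66).

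Young BAM15 3 lay above the others of its group in the mitochondrial share (%) 9.27 (5.39 to 5.88), glycolysis and hypoxia genes 5.58 (4.46 to 4.602), skeletal muscle genes 11.10 (1.02 to 3.20) and Cox8b 8.21 (4.81 to 5.78). Young BAM15 1 lay below the others of its group in macrophage genes 4.52 (5.40 to 5.69), B cell genes -0.51 (4.99 to 6.98), lymph node stroma genes -0.023 (4.14 to 6.402), Ighd 0.41 (6.11 to 8.38), Cdkn2a -1.77 (0.82 to 1.79) and Kcnk1 -2.19 (-0.54 to -0.067). Young BAM15 5 lay below the others of its group in collagen and extracellular matrix genes 6.79 (7.46 to 7.73) and Col3a1 8.96 (9.94 to 10.20). Young BAM15 2 lay above the others of its group in Per1 5.24 (3.84 to 4.22). Young BAM15 6 lay above the others of its group in Adam33 4.98 (4.22 to 4.50).

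Aged CTRL 2 lay above the others of its group in the mitochondrial share (%) 14.6 (4.82 to 7.64), cytotoxic and exhausted lymphocyte genes 2.34 (0.32 to 0.80), Mcpt4 7.42 (1.97 to 3.79), Psmb8 8.39 (5.77 to 6.19) and Tef 9.31 (6.87 to 7.40), and below them in the number of genes detected 14564 (16194 to 16572), mitochondrial biogenesis and dynamics genes 4.25 (4.90 to 5.15), endoplasmic reticulum stress genes 4.83 (6.19 to 6.30), senescence and secretory factor genes 2.41 (3.20 to 3.64) and Lep 7.56 (10.66 to 12.25). Aged CTRL 1 lay above the others of its group in Cox8b 6.38 (4.16 to 4.96), and below them in Fasn 6.33 (8.02 to 8.67), Col5a3 6.72 (7.79 to 8.06) and Cdk1 2.65 (4.10 to 4.601). Aged CTRL 6 lay below the others of its group in Pcna 3.75 (4.44 to 4.70).

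Aged BAM15 5 lay above the others of its group in Ttc39c 3.00 (2.51 to 2.65), and below them in cell cycle genes 0.43 (1.52 to 1.95). Aged BAM15 2 lay above the others of its group in Ctss 7.42 (6.48 to 6.72), Dbp 6.87 (5.53 to 5.84), Mrgprg 3.91 (2.93 to 3.05) and Ugt2b36 0.058 (-2.78 to -2.04), and below them in Cdkn1a 2.86 (5.48 to 5.92). Aged BAM15 4 lay above the others of its group in Ucp1 -0.46 (-2.78 to -2.78). Aged BAM15 1 lay above the others of its group in Trem2 3.45 (1.00 to 1.70).

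BAM15 changes of 19 lists differed between aged and young mice by camera with the preset correlation, and 0 of them with an estimated correlation. Values are the mean log2 difference, with the BAM15 changes in aged and in young mice in brackets. Between the ages, the mean BAM15 change differed for de novo lipogenesis 0.47 (-0.031 and -0.50), triglyceride synthesis and lipolysis 0.36 (-0.071 and -0.43), mitochondrial respiratory chain (nuclear) 0.30 (0.018 and -0.28), mitochondrial genome encoded 0.66 (0.25 and -0.40), TCA cycle and branched chain amino acids 0.59 (0.33 and -0.25), cholesterol synthesis 1.35 (-0.28 and -1.62) and circadian clock 0.39 (0.30 and -0.091). It also differed for macrophage -0.46 (-0.45 and 0.011), lipid-associated macrophage -0.51 (-1.23 and -0.72), dendritic cell and antigen presentation -0.74 (0.14 and 0.88), B cell -0.97 (1.179 and 2.15), plasma cell -1.46 (-0.13 and 1.33), T cell -0.040 (1.79 and 1.83) and cytotoxic and exhausted lymphocyte -0.63 (0.67 and 1.29). It differed as well for lymph node stroma -0.76 (1.31 and 2.07), endothelial -0.54 (-0.37 and 0.17), interferon response -0.91 (-0.49 and 0.42), skeletal muscle -0.47 (-0.34 and 0.13) and epithelial and mammary gland 3.58 (0.47 and -3.11). For skeletal muscle genes the sign of the mean and the direction of the test, which used log2 CPM, differed, and the mean of T cell genes was near 0. On log2 CPM the T cell list differed by 1.17 with BAM15 in aged and by 2.29 in young mice. Single libraries carried several of these values, which then lost their call: cholesterol synthesis lay at 0.29 and epithelial and mammary gland at 1.24 without Young CTRL 1, and the latter at 0.27 without Young CTRL 1 and 7, the libraries with skin keratin. Skeletal muscle lay at -5.33 without Young CTRL 7, and B cell at 0.43, lymph node stroma at 0.19 and cytotoxic and exhausted lymphocyte at -0.0071 without Aged CTRL 2. Plasma cell kept its call and lay at -2.42 without Young CTRL 1, with a BAM15 change in young mice of 2.29.

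Other splits of the same libraries into groups of the same sizes were run, 100 for each result with the real one included. Their shares are not adjusted over the results tested. For age, 1 of 100 splits gave as many genes as the real 33, with 14 as the highest of the others, which argues against chance for that count. For BAM15 in young mice, 2 of 100 gave as many genes with an unadjusted p under 0.05 (2081, highest other 2088). As many lists came from 1 of 100 (24, highest other 23). Few splits reached either value, but these shares alone do not exclude chance. Nor do they show the source of the excess. With the B cell and muscle covariates these counts were 806 and 8, and without Young BAM15 5 the first was 1184. The splits were not run in these fits. For the interaction, 3 of 100 gave as many lists (19, highest other 23), which alone does not exclude chance. That count was 6 without Aged CTRL 2, 7 without the 4 libraries with low mt-Rnr2 and 10 with the covariates.

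Chance cannot be excluded for these results either, which more splits reached. For age, 14 of 100 splits gave as many lists (15, highest other 22). For BAM15 in aged mice, 21 gave as many genes at an unadjusted p under 0.05 (1450, or 3055 without Aged CTRL 2, highest other 5283) and 9 as many lists (14, highest other 15). For the interaction, 37 gave as many genes at an unadjusted p under 0.05 (809, or 2111 without Aged CTRL 2, highest other 3450). For Aged BAM15 against Young CTRL, 8 of 100 gave as many genes (205, highest other 2622) and 46 as many lists (11, highest other 19). The other splits that reached 205 genes had all 3 libraries of low mt-Rnr2 on one side, unlike the real one. That share therefore cannot decide about chance for this count. For BAM15 in aged mice, the 18 splits grouped in that way all passed 1450, and so did 2 others (1707 and 1785). For age opposed by BAM15, 86 gave as negative a correlation (r = -0.356, most negative other -0.771). For BAM15 at both ages, 20 of 100 gave as strong a correlation (r = 0.312, strongest other -0.610). Where the real count of genes was 0, 100 of 100 splits gave as many by construction, which says nothing about chance: the highest other was 2794 for BAM15 in aged mice, 0 for BAM15 in young mice, 243 for the interaction and 98 for age opposed by BAM15.

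Splits that called many more genes than the real one point to a structure of the samples. For BAM15 in aged mice, the 18 splits with all 3 libraries of low mt-Rnr2 on one side reached 2794 genes, and the rest at most 1. For Aged BAM15 against Young CTRL, the 23 such splits reached 2622 genes and the rest at most 9, while the real split has 2 of the 3 on one side and gave 205.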

How the results depend on the processing

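Fits without the 4 libraries with low mt-Rnr2, without the 2 with skin keratin, and with a term for the 4, alone or with both tissue covariates, were chosen only after the data were seen. A fit to the compared groups alone was not run for the interaction, which needs all 4 groups. Under DESeq2 size factors, upper-quartile factors, no filter, the stricter filter, the limit of 1 on the log2 change and 1 surrogate variable, the counts were 33 to 40 genes for age, 157 to 223 for Aged BAM15 against Young CTRL, and 0 for BAM15 in aged mice, BAM15 in young mice and the interaction. Except for the leave-one-out fits, 2100 of the values of named genes kept their direction and side of the threshold, 81 fell short of it, 76 passed it and 52 changed direction. For lists, 491 kept both, 234 fell short and 14 changed direction. Values below are counts or log2 changes, and the genes that changed sign were not called in edgeR with all libraries. The cause was not tested unless stated.

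With DESeq2 size factors, the value of Ucp1 for BAM15 in young changed sign, at 0.0043. With the DESeq2 test, the counts of genes were 271 for age, 140 for BAM15 in aged, 218 for BAM15 in young, 38 for the interaction, 826 for Aged BAM15 against Young CTRL and 31 for age opposed by BAM15. The value of Ucp1 for BAM15 in young changed sign, at 0.030. With limma-voom with quality weights, the counts of genes were 147 for age, 964 for BAM15 in aged, 679 for BAM15 in young, 1633 for Aged BAM15 against Young CTRL and 31 for age opposed by BAM15. Values that changed sign were, for age, Psmb8 -0.038, for BAM15 in aged, Hadh -0.041 and Cdkn2a 0.66, for BAM15 in young, Scd1 0.094, and for the interaction, Lep 0.39 and Adipoq -0.47. With a fit to the groups compared, the counts of genes were 18 for age and 29 for Aged BAM15 against Young CTRL. With the replicate block, the counts of genes were 5 for age and 17 for Aged BAM15 against Young CTRL, and the count of lists was 12 for the interaction. These changed sign, for age, Ucp1 0.020, for BAM15 in aged, Cdkn2a 0.10, for BAM15 in young, Ucp1 0.59, and for the interaction, Gdf15 0.47.

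With 1 surrogate variable, values that changed sign were, for the interaction, Lep 0.057 and Gdf15 0.0084. With the B cell and muscle covariates, the counts of genes were 54 for age and 7 for BAM15 in young, and the counts of lists were 8 for BAM15 in young and 10 for the interaction. Sign changes were, for BAM15 in young, Dendritic cell and antigen presentation -0.22, T cell -0.062, Ighd -0.78, Bcl11b -0.51, Cd52 -0.21, Scd1 0.041 and Cdkn2a -0.57, for the interaction, T cell 0.76, Cytotoxic and exhausted lymphocyte 0.29, Lymph node stroma 0.25, Adipoq -0.15 and Gdf15 0.23, and BAM15 in aged: Irf1 -0.00695. With the estimated correlation of camera, the counts of lists were 3 for age, 1 for BAM15 in aged, 0 for BAM15 in young, 0 for the interaction and 5 for Aged BAM15 against Young CTRL. With fry, the counts of lists were 5 for age, 1 for BAM15 in aged, 4 for BAM15 in young and 0 for the interaction.

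Without the 4 libraries with low mt-Rnr2, the counts of genes were 79 for age and 105 for Aged BAM15 against Young CTRL, and the counts of lists were 23 for age and 7 for the interaction. Sign changes were, for BAM15 in aged, TCA cycle and branched chain amino acids -0.024, Hadh -0.22, Igfbp4 -0.022 and Cdkn2a 0.59, for the interaction, Mitochondrial respiratory chain (nuclear) -0.054, T cell 1.14, Lep 0.45 and Adipoq -0.51, for age, Psmb8 -0.053, Irf1 0.095, Ucp1 0.76 and Cdkn1a 0.018, and for BAM15 in young, Ucp1 1.81. Without the 2 libraries with skin keratin, the counts of genes were 4 for age and 86 for Aged BAM15 against Young CTRL, and the count of lists was 17 for Aged BAM15 against Young CTRL. These changed sign, for age, Adipoq -0.079, and for the interaction, Lep 0.20. With a term for those 4 libraries, the counts of genes were 91 for age, 5 for BAM15 in aged, 2 for BAM15 in young, 356 for Aged BAM15 against Young CTRL and 1 for age opposed by BAM15. Values that changed sign were, for BAM15 in aged, Hadh -0.060, for BAM15 in young, Scd1 0.057 and Ucp1 1.01, and for the interaction, Lep 0.74 and Adipoq -0.34. With that term and both covariates, the counts of genes were 194 for age, 9 for BAM15 in aged, 440 for Aged BAM15 against Young CTRL and 4 for age opposed by BAM15, and the counts of lists were 9 for BAM15 in young and 8 for the interaction. Sign changes were, for BAM15 in young, TCA cycle and branched chain amino acids 0.0088, Dendritic cell and antigen presentation -0.19, T cell -0.12, Ighd -0.72, Bcl11b -0.45, Cd52 -0.31, Scd1 0.18, Ucp1 0.13, Adipoq 0.075 and Cdkn2a -0.63, for the interaction, Mitochondrial respiratory chain (nuclear) -0.11, T cell 0.997, Lymph node stroma 0.34, Lep 0.48, Adipoq -0.60, Cdkn2a 0.039 and Gdf15 0.16, and for BAM15 in aged, Psmb8 -0.023 and Irf1 -0.0073.

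The direction of a list is that of camera, which compares its members with other genes on log2 CPM. The mean log2 change instead averages the fitted changes of the members, and the 2 measures can differ in sign. For BAM15 in aged mice, the mean log2 CPM of skeletal muscle genes differed by 1.91, while their mean log2 change was -0.34. The mean log2 change of some lists changed sign where that direction did not. Without Young CTRL 1 and 7 these were, for BAM15 in young, creatine and calcium cycling 0.32, glycolysis and hypoxia 0.17 and epithelial and mammary gland 0.54. Without the 4 libraries they were, for the interaction, B cell 0.83 and lymph node stroma 0.67. With the term for the 4 libraries, skeletal muscle lay at 0.71 for BAM15 in aged and 0.70 for the interaction, and T cell at 0.026 for the interaction. With that term and both covariates, antioxidant lay at 0.0016 for BAM15 in young and cytotoxic and exhausted lymphocyte at 0.057 for the interaction. With the replicate block, skeletal muscle lay at 0.45 for BAM15 in aged and T cell at 0.33 for the interaction, and with 1 surrogate variable skeletal muscle lay at 0.55 and 1.4 for the same 2. Single libraries did so too: creatine and calcium cycling lay at 0.28 for BAM15 in young without Young CTRL 7, skeletal muscle at 1.96 for BAM15 in aged and 1.83 for the interaction without Aged CTRL 1 and at 5.99 for the interaction without Young BAM15 3, and B cell at 0.43 and lymph node stroma at 0.19 for the interaction without Aged CTRL 2. The mean of T cell for the interaction was above 0 in 12 of the fits that left out 1 library.

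Leaving out 1 library at a time gave these ranges: for age, the count of genes 20 to 35, Kcnk3 -0.25 to 0.062, Mcpt4 -0.37 to 3.07, Pcna -0.12 to 0.062 and Cdkn1a -0.55 to 0.12; for BAM15 in aged, the count of genes 0 to 67, Apoe -0.098 to 0.43, Pcna -0.19 to 0.088, Psmb8 -0.27 to 0.85, Irf1 -0.058 to 0.36, Fasn -0.47 to 0.059 and Cdkn2a -0.58 to 0.17; for BAM15 in young, the count of genes 0 to 1, Scd1 -0.19 to 0.12 and Ucp1 -0.22 to 0.26. They were, for Aged BAM15 against Young CTRL, the count of genes 46 to 630, the count of lists 9 to 19 and Pcna -0.23 to 0.039; for age opposed by BAM15, the count of genes 0 to 1; and for the interaction, the count of lists 6 to 21, Lep -0.33 to 0.29, interaction of age and BAM15: Adipoq -0.0769 to 0.26 and Gdf15 -0.34 to 0.26. The lowest count for age came without Aged CTRL 6, and the highest counts for BAM15 in aged and for Aged BAM15 against Young CTRL came without Aged BAM15 1 (67 and 630). Fewer libraries lower the power of these fits by construction. The correlation of BAM15 changes at both ages ran from 0.149 without Aged BAM15 4 to 0.399 without Aged BAM15 5.

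Depth set a limit for genes with few counts: 1602 genes were not tested, and Ucp1 had a mean of 0.117 CPM in Aged BAM15. In data simulated with the spread between these mice, 5 of 50 genes changed 2-fold with age were called and 27 of 50 changed 4-fold.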

Other observations

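The single genes of this part were chosen after their values were seen, and only their levels are given here.

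Transcripts of neighbouring tissue differed between libraries of the same group. The B cell list had a mean log2 CPM of 5.22 and 5.25 in Young CTRL 1 and 5, of 4.99 to 6.98 in Young BAM15 2 to 6 and of -0.51 in Young BAM15 1. In aged mice it was 4.54 in Aged CTRL 2, 4.06, 4.18 and 4.97 in Aged BAM15 2, 3 and 4, and at most 2.73 in the other aged libraries. Acta1, of skeletal muscle, lay at 14063 CPM in Young CTRL 7, 14545 CPM in Young BAM15 3, 5891 CPM in Aged CTRL 1, 2169 CPM in Aged BAM15 1 and 1442 CPM in Aged BAM15 2, and at most 896 CPM in the others. Krt14, of skin, lay at 840 CPM in Young CTRL 1 and 90.0 CPM in Young CTRL 7. Hbb-bs, a haemoglobin gene of blood, lay at 35517 CPM in Aged BAM15 2 and at 699 to 5347 CPM in the other 23 libraries.

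Single abundant transcripts set the 4 libraries with low mt-Rnr2 apart. Malat1, a nuclear RNA, lay at 135 to 183 CPM in them and at 2438 to 19691 CPM in the other 20. Gm42418, which overlaps ribosomal RNA, lay at 151 to 894 CPM against 56393 to 188687 CPM. The mitochondrial gene mt-Nd4 lay at 70194 to 152802 CPM against 8255 to 30376 CPM. Not every such transcript did so: Neat1, another nuclear RNA, lay at 640 to 1751 CPM in the 4 and 433 to 1973 CPM in the others, and mt-Co1 at 666 to 1161 against 670 to 1930 CPM.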
